A study of Homo sapiens with 18 samples.

How the data were processed

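Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in 18 libraries of HCT116, a human colon cancer cell line, in which INTS11 carries an auxin-inducible degron tag (INTS11-AID). INTS11 is the endonuclease subunit of Integrator, a complex that cleaves transcripts of RNA polymerase II (Pol II). IAA is auxin, which triggers degradation of the tagged protein. The antibodies recognised Pol II, its C-terminal domain phosphorylated at tyrosine 1 (Tyr1P), or that domain phosphorylated at serine 2 (Ser2P). Per the labels' protocols, which give 1 text for all samples, cells were held without serum for 14 h, and treatments were 500 µM IAA for 1 h, 100 ng per µl EGF for 30 min and 2000 U interferon beta for 1 h. The same text does not say which library received which treatment, so groups were taken from the titles.

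Per the submitters' processing notes, the tools were Trim Galore 0.6.6, Bowtie2 2.3.4.1, Picard 2.25.7, deepTools 3.5.1 and MACS2 2.2.7.1, and the genome build was hg38. Their options, filters and the use of the inputs as control are not given in the sources used here. The authors deposited 1 peak list per library, so peaks were called per sample. Each deposited list gives a peak's fold enrichment at the summit, its −log10 p and −log10 q, a score and the summit position. The lowest deposited −log10 q over all lists was 1.31. These deposited fold, −log10 and score values belong to each peak within its own list. They were used here to describe, rank or filter peaks of that list and were not themselves compared between libraries. Depth, local background and stacked fragments were estimated from the fold and p, as given below, and these estimates were compared between libraries.

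The deposited peak lists hold no read totals. Depth was therefore estimated. The deposited fold and −log10 p were solved for the fragments stacked at the summit and the local background, taking the fold as a ratio with 1 added to both terms and the p as a Poisson tail. A whole number of fragments matched the deposited p within a relative tolerance of 0.0002 for 100% of peaks in every list. The lowest background shared by several peaks was taken as the library's genome-wide background, and this divided by the shortest peak width gives fragments per kb. It ranged from 2.94 in Pol II Control replicate 1 to 13.6 in Ser2P Control replicate 1. The highest stack in each list lay at or near 2 fragments per position over the shortest peak width (380 of 380 in Pol II Control replicate 1), except in Ser2P Control replicate 2 (434 of 522), so the strongest peaks can be flattened at a limit and their summits are then less certain. On 5000 simulated peaks the solution returned the simulated fragments for 100%.

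Peaks on chromosomes 1 to 22 and X were kept, and peaks sharing at least 1 bp with a peak of either input library were removed, which took 0.276% to 2.31% of a list. Genes came from a table of NCBI RefSeq on GRCh38.p14 with 19974 protein-coding genes on these chromosomes. That table gives no strand, so the planned distance from the gene start was replaced. A summit within 1 kb of either end of a protein-coding gene was called an edge peak. A summit more than 1 kb inside both ends was called interior, for genes of at least 2 kb. A summit outside a gene and up to 5 kb from an end was called a flank peak, and the rest lay elsewhere. For profiles along genes, 8272 genes of at least 5 kb were read from the end that held an edge peak in at least 8 of the 12 Pol II and Tyr1P libraries, with at most 1 such library at the other end. As a check, the strands of 36 genes were written down from general knowledge, not from an annotation. Of these genes 17 were so oriented, 16 in the known direction and 1 opposite. This orientation was chosen after seeing the data.

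The overlap of peak lists of different antibodies was the share of all peaks of both lists that shared at least 1 bp with the other list, in place of the planned Jaccard index. Percentages of genes with peaks of 2 antibodies compare libraries of the same replicate number. Library values were compared by a two-sided exact permutation test. With 2 libraries against 2, this exact test cannot go below p = 0.333, and within pairs not below 0.5. A gene was called gained with a peak in both IAA libraries and neither control library, and lost in the reverse case. These counts were set beside the same counts in the other splits of the 4 libraries. On simulated presence at the edges of 19974 genes, made from the Tyr1P controls with 100 genes changed each way and 2% of calls flipped at random, 90% of the gained and 90% of the lost genes were found, with 4 and 8 false calls. These rates follow largely from the flip rate that was set. They do not carry over to Pol II or Ser2P, whose replicates differed more (6675 and 2903 genes with interior peaks in the Ser2P controls). Of 502 listed symbols in 19 gene lists, 501 were matched. The result for 1 of the listed genes is not reported here. Each list was tested by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 114 tests. Genes gained were tested against genes with no peak in either control library, and genes lost against genes with a peak in both. Genes are not independent replicates, so these tests describe these libraries. For single libraries, list counts were placed among 10000 random lists matched on the decile of peak rank in the reference library.

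Groups, tests, gene lists and the rule for named genes were set before the data were examined. The rule took, per comparison and in its main region, the 6 gained and 6 lost protein-coding genes with the highest mean percentile of −log10 q, the 4 highest with a peak in all 4 libraries, 4 gained and 4 lost genes for each of 2 EGF comparisons, and 20 fixed genes. The main region was the edge for Pol II and Tyr1P and the interior for Ser2P. Alternatives were a stricter threshold (−log10 q of at least 5), lists cut to equal length, an edge window of 500 bp, any overlap in place of the summit, input-overlapping peaks kept, a replicate block, each replicate left out, and the unnumbered libraries added. Not every alternative applied to every result. Joining of peaks and a restriction to the oriented genes were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Nothing in the labels says that replicates came from separate cultures. The permutation p-values therefore measure only the spread between these libraries, which may be technical. Fisher's exact tests count genes and hold no spread between libraries.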

Results

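Peak lists of 16 immunoprecipitated and 2 input libraries were compared. Control and IAA had 2 numbered libraries each for Pol II, Tyr1P and Ser2P. A further 4 Pol II libraries without replicate numbers were labelled Control, IAA, EGF and IAA+EGF, with 1 library each. The depth estimated from the lists ranged from 2.94 to 13.6 fragments per kb over the immunoprecipitated libraries. The title and the file name of the libraries labelled IAA and EGF name different treatments, so both are called by their labels. Input lists held 1579 and 1004 peaks, against 15420 to 99476 in the immunoprecipitated libraries. The degron acts on the INTS11 protein, so no value here checks its loss. The INTS11 gene itself, on chromosome 1, had an edge peak in all 4 numbered libraries for Pol II and for Tyr1P.

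The first question was how the distribution of Pol II changed with IAA. Fewer Pol II peaks were called with IAA, 20383 ± 3784 (SD, n = 2) against 24829 ± 3309 (SD, n = 2) in Control, but the groups overlapped (exact permutation p = 0.667). The edge share was 54.8% ± 4.98 (SD, n = 2) with IAA and 49.8% ± 3.88 (SD, n = 2) in Control (exact permutation p = 0.667). Leaving out 1 library gave an IAA minus Control difference of 1.47 to 8.51 percentage points. With lists of equal length this difference turned, to -2.79 percentage points. Edge peaks at 603 genes were lost and at 68 genes gained, while the other splits of the same libraries gave at most 95 genes. The lost count thus lay above the other splits and the gained count did not. Without IAA replicate 2, 1558 genes were lost. The gained count was 184 without IAA replicate 1, 104 without IAA replicate 2, 148 without Control replicate 2, 148 with lists of equal length and 136 with a window of 500 bp. With the unnumbered libraries labelled Control and IAA added, 22 genes were lost and 3 gained, but the title of the added IAA library is in doubt. Of the 603 lost genes, 35 lacked an edge peak in that library and 18 in the unnumbered Control. In the libraries labelled EGF and IAA+EGF, 89 and 95 of them lacked one. Most of the 603 thus kept an edge peak in each of these libraries, whichever titles hold. These lists were longer, with 27701 to 35424 peaks, than the numbered IAA lists, with 17707 and 23059. A kept peak can therefore reflect list length, which was not held equal. Of all 12233 genes with an edge peak in the unnumbered Control, 526 lacked one for the label EGF and 324 for IAA.

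The 6 highest-ranked genes that lost Pol II edge peaks were PARP2 (a DNA repair enzyme, chromosome 14, 20343635 to 20357904), C12orf57, S100A1, LOC124900418, C1QTNF6 and RPL13, a ribosomal protein. At PARP2 the deposited fold was 20.3 and 20.2 within the 2 control lists. The gained genes were TMEM107 (chromosome 17, 8172457 to 8176380), SIN3A, a transcriptional corepressor, LOC124903857, WDR88, DMAC2L and PRR20G. These calls follow summit positions, and peaks remained nearby at several of them. At PARP2 the nearest summits with IAA lay 453 and 461 bp from RPPH1, the neighbouring RNase P RNA gene, on which the control summits lay. At C12orf57 they lay 631 and 732 bp from RNU7-1 inside it, against 90 and 151 bp in Control. At TMEM107 they lay 386 and 380 bp from SNORD118, on which the control summits lay. These 3 neighbours were chosen after their values were seen. The highest-ranked genes with peaks in all 4 libraries were SOCS1, DGAT1, ZBTB4 and POLR2A, the largest Pol II subunit. ZBTB4 and POLR2A share 1 peak between their ends.

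Of 48 immediate early genes, which growth factors switch on rapidly, 43 had a Pol II edge peak in all 4 libraries and 0 were gained or lost. FOS, EGR1, JUN, MYC, IER2, DUSP1 and NR4A1 were among the genes with a peak in all 4. Of 59 replication-dependent histone genes, 39 had a peak in all 4, H4C3 included, and 2 were lost, H4C1 and H3C6. Of 20 snRNA genes, 13 had a peak in all 4, RNU1-1 and RNU2-1 included, and RNU2-2 and RNU4-1 were lost. MDM2, CDKN1A, GAPDH and NEAT1 had edge peaks in all 4 libraries, whereas ACTB and KLF6 had none in IAA replicate 1. ATF3 had interior but no edge peaks. HBB, a globin gene, had an edge peak in 1 control library, and of 15 blood cell genes 0 had one in all 4.

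**Figure D1:**
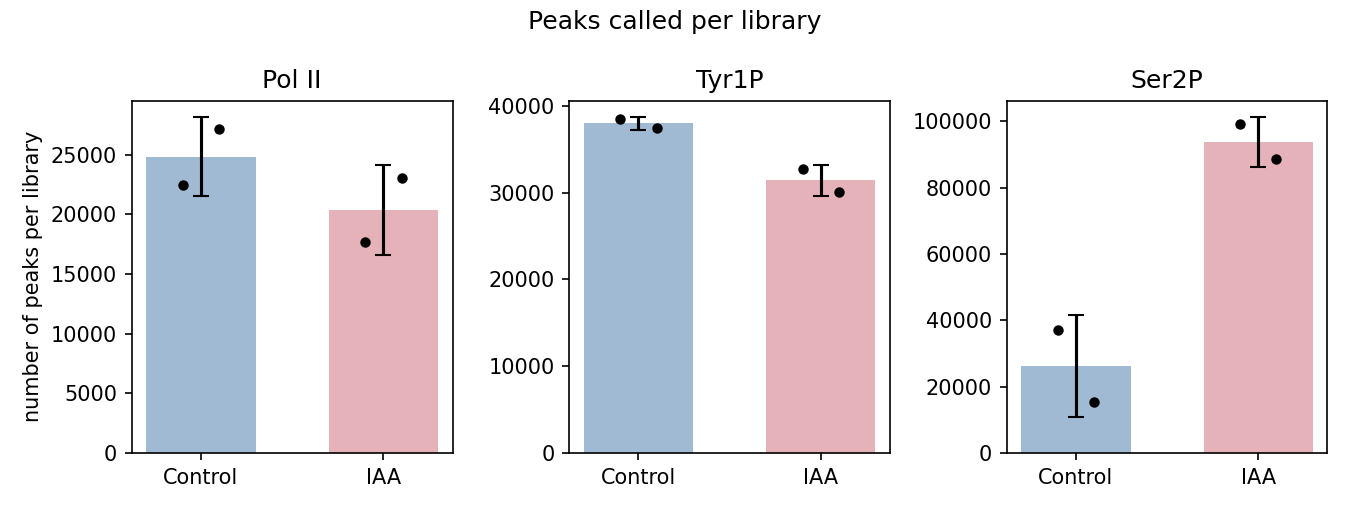
Number of peaks per library (vertical axis, with its own scale for each antibody) for Pol II, Tyr1P and Ser2P, with bars for the mean, error bars for the SD and points for the 2 libraries of each group. Ser2P libraries with IAA held 88503 and 99001 peaks, above both control libraries.

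The second question concerned Tyr1P. Tyr1P peaks were fewer with IAA, 31409 ± 1812 (SD, n = 2) against 37979 ± 716 (SD, n = 2), with no overlap of the groups (exact permutation p = 0.333, the smallest this design allows). The edge share was 41.3% ± 1.67 (SD, n = 2) with IAA and 35.4% ± 1.11 (SD, n = 2) in Control, and the interior share 25.5% ± 0.693 against 28.2% ± 0.314 (both SD, n = 2; exact permutation p = 0.333 for each). The number of edge peaks was nevertheless lower with IAA, 12961 ± 226 against 13450 ± 167 in Control (both SD, n = 2). With lists of equal length the difference in edge share was 1.65 percentage points. Edge peaks were lost at 296 genes and gained at 84, against at most 34 in the other splits. Lists of equal length gave 132 gained genes. Leaving out 1 library gave 137 to 182 gained genes, and 487 lost genes without IAA replicate 1.

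The 6 highest-ranked lost genes were S100A1 (a calcium-binding protein, chromosome 1, 153628434 to 153632039), C12orf57, NECAB3, SMCO3, ADCY9 and TNPO3. S100A1 and C12orf57 were also among the named genes lost for Pol II. The gained genes were NDUFAF3, LUC7L2, FMC1, ARSB, MZT2A and PHPT1, of which LUC7L2 and FMC1 share 1 peak. CRISPLD2, CSRNP2, OAT and DNAJC25-GNG10 ranked highest among genes with peaks in all 4 libraries. Of 48 immediate early genes 45 had a Tyr1P edge peak in all 4. Of 20 snRNA genes 15 did, and RNU5F-1, RNU2-2 and RNU5A-1 were lost (Fisher's exact p = 0.0104, adjusted p = 0.396). Of 15 Integrator subunits 15 had peaks in all 4. Tyr1P edge peaks were present at 99.2% ± 0.328 of genes with a Pol II edge peak in Control and 99.0% ± 0.233 with IAA (both SD, n = 2).

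The third question concerned Ser2P, a mark of elongating Pol II. Ser2P peaks were 3.59 times as many with IAA, 93752 ± 7423 (SD, n = 2) against 26142 ± 15375 (SD, n = 2), with no overlap of the groups (exact permutation p = 0.333, the smallest this design allows). Control replicate 2 was the shallowest Ser2P library. Without it the ratio was 2.53, and without Control replicate 1 it was 6.14. The interior share of peaks was 54.4% ± 1.07 with IAA and 26.4% ± 8.13 in Control, and the edge share 18.4% ± 0.916 against 49.0% ± 14.1 (all SD, n = 2; exact permutation p = 0.333 for each). The number of edge peaks was nevertheless higher with IAA, 17253 ± 510 against 11733 ± 3859 in Control (both SD, n = 2). Interior peaks were gained at 3699 genes and lost at 29, and the other splits gave at most 162. Without Control replicate 1, 7090 genes were gained, and without Control replicate 2, 263 were lost. With lists cut to the 15270 highest-ranked peaks, the edge share differed by 0.272 percentage points, and 331 genes were gained and 322 lost. Cutting to 1 length removes the difference in peak number itself.

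Genes with interior Ser2P peaks numbered 6675 and 2903 in the control libraries and 10964 and 10533 with IAA. Among 8272 genes read from their Pol II-marked end, interior summits of all called peaks numbered 36061 ± 3593 with IAA and 4763 ± 4214 in Control (both SD, n = 2). Over 10 equal bins of the interior the ratio of the means was 4.43 in the first bin, 5.93 in the last and at least 8.05 in each bin between them. Without Control replicate 2 these 3 values were 2.87, 3.71 and 4.89, and without Control replicate 1 they were 9.74, 14.9 and 22.9. At the Pol II-marked end itself the numbers were 8831 ± 144 and 7280 ± 1766 (both SD, n = 2). Among genes with a Pol II edge peak, 69.0% ± 1.87 had an interior Ser2P peak with IAA and 29.2% ± 18.1 in Control (both SD, n = 2). Among genes without one, the values were 36.5% ± 3.62 and 16.8% ± 7.03 (both SD, n = 2). Both sets include genes under 2 kb, which can hold no interior peak, so gene length can affect this contrast.

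**Figure D2:**
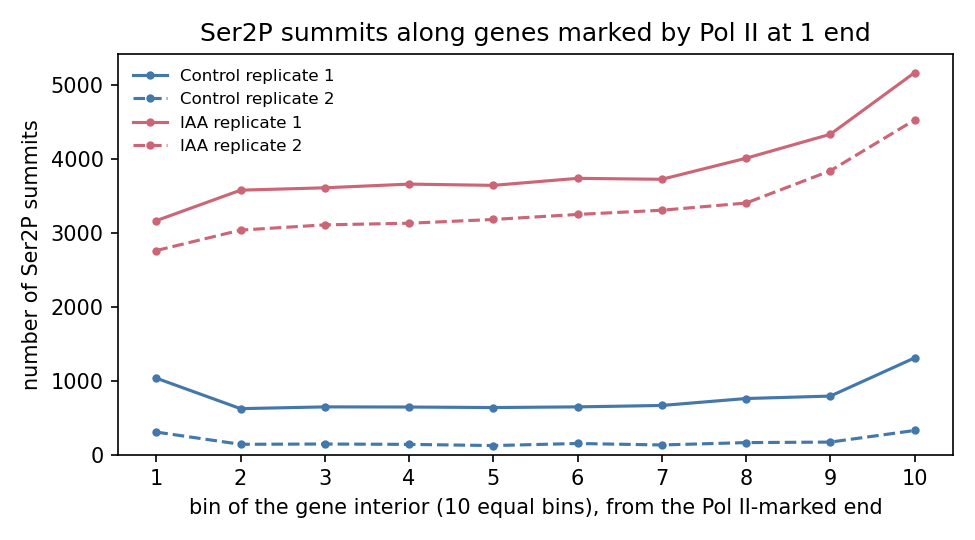
Number of Ser2P peak summits (vertical axis) in 10 equal bins of the gene interior (horizontal axis, from the Pol II-marked end) over 8272 genes, with 1 line for each of the 4 Ser2P libraries. The mean of the IAA libraries was 4844 in the last bin, against 817 in the control libraries.

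The 6 highest-ranked genes that gained interior Ser2P peaks were C12orf57 (chromosome 12, 6943433 to 6946003), TEX2, ZSWIM7, RPL27A, NDUFB10 and SDR42E2. At C12orf57 the nearest Ser2P summits lay 344 and 526 bp from RNU7-1 in Control and 626 and 646 bp with IAA, so a peak was also near in Control. The lost genes were LONRF1, TMEM107, TRIM47, CYC1, KLF10 and WWC3. CYRIB, RPL17-C18orf32, NTMT1 and CHD2, a chromatin remodeller, ranked highest among genes with peaks in all 4 libraries. Of 28 pausing and elongation factors, 17 had no interior peak in either control library and 12 of these were gained, 70.6% against 31.0% of all such genes (Fisher's exact p = 0.000895, adjusted p = 0.102, past no threshold after adjustment). The gained factors included CCNT1 and CCNT2, cyclins of the elongation kinase P-TEFb, NELFA and SUPT5H. The base of all such genes was not matched for Pol II. With IAA, interior Ser2P peaks were found at 69.0% of genes with a Pol II edge peak and 36.5% of those without. These shares include genes with a control peak and genes under 2 kb, so they cannot be set against the 70.6%. Of the 28 factors, 24 had a Pol II edge peak in all 4 libraries. The contrast may reflect that in part or alone, and how much was not tested. On the same base of genes without a control peak, 8 of 13 cleavage and termination factors were gained (Fisher's exact p = 0.0302, adjusted p = 0.688). Of Integrator subunits 5 of 9 were gained (55.6%, Fisher's exact p = 0.147) and of ribosomal protein genes 16 of 48 (33.3%, Fisher's exact p = 0.755). Of immediate early genes 7 of 19 were gained (36.8%, Fisher's exact p = 0.621), JUN among them, while KLF10 was lost. These shares lay near the 31.0% of all such genes or rested on few genes. Over the 3 antibodies and both directions, 0 of 114 list tests by Fisher's exact test had an adjusted p under 0.05, and 6 had an unadjusted p under 0.05. Of 11 blood cell genes 0 were gained (Fisher's exact p = 0.0223, adjusted p = 0.634).

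The fourth question was the response of Pol II to EGF, a growth factor, with and without IAA. It rests on 1 library per label, with no replicate check and no test. The libraries labelled Control, IAA, EGF and IAA+EGF held 35424, 33226, 27701 and 28921 peaks. In the library labelled EGF, edge peaks at 165 genes were gained and at 526 lost against Control, and in the library labelled IAA 201 and 324. Lists of equal length gave 294 gained and 309 lost for the label EGF. The library labelled IAA+EGF gained 264 and lost 267 against the label EGF, and gained 223 and lost 464 against the label IAA.

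The highest-ranked genes gained in the library labelled EGF against Control were NDUFAF3, PPM1L, FLOT1 and PEX2, and those lost were SLC2A11, ADGRF3, H1-4 and FAM118A. In the library labelled IAA+EGF against the label EGF, H1-4, ARL6IP6, WDR88 and ZBTB43 were gained, and S100A1, SCAF8, SMCO3 and SIRT4 lost. FOS, EGR1, JUN, MYC, IER2, DUSP1, NR4A1 and KLF6 had Pol II edge peaks in all 4 unnumbered libraries. Of 48 immediate early genes, 0 were gained and 1 lost in the library labelled EGF against Control, at percentiles 47.0 and 59.7 of random lists. For the label IAA 0 were gained or lost. Presence leaves little room for a gain, since 3 of the 48 had no edge peak in either numbered Pol II control library. A rise of Pol II at a gene that already held a peak is not seen by this measure. In the library labelled IAA+EGF, 2 of the 48 immediate early genes were gained and 0 lost against the label EGF, at percentile 99.7 for the gained count. Against the label IAA 1 of them was gained and 0 lost. Of 15 neuron genes, 2 were gained and 1 lost for the label EGF against Control, and 2 were gained and 2 lost for the label IAA against Control. Their gained counts lay at percentiles 99.3 and 99.0. Percentiles were taken for 19 lists in each comparison and both directions without adjustment, so high values on 1 or 2 genes are not evidence of a response. In the library labelled IAA+EGF, 0 were gained and 2 lost against the label EGF, and 0 gained and 1 lost against the label IAA. IFIT1, an interferon-stimulated gene, had an edge peak in all 4.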

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

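All tests in this part except the one on snRNA genes were chosen after the result was seen. The number of Ser2P peaks moved the opposite way from Tyr1P between Control and IAA, in every library of both antibodies. On the log2 scale the change of the mean was 2.252 larger for Ser2P than for Tyr1P. Permuting the labels within each antibody gave p = 0.0556 (exact permutation over 36 arrangements), the smallest these arrangements can give, so this test could not pass 0.05.

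For the rise in Ser2P peaks, the tables argue against 2 technical explanations. Peaks per unit of depth were 1.81 times as many in the lower IAA library as in the higher control library, and the deepest Ser2P library was a control. Joining peaks within 5 kb left 1.90 times as many domains in the lower IAA library as in the higher control library, so cutting of broad domains alone does not account for the rise. The local background around peaks, relative to each library's own floor, was 0.588 times that of Control in the IAA libraries. A lower background may have eased calling and cannot be told apart from a change in Ser2P, because no background independent of the calls is held, and immunoprecipitation efficiency and an effect of IAA stay open, untested.

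Estimated depth was 7.23 ± 0.298 (SD, n = 2) fragments per kb in the Tyr1P IAA libraries and 6.78 ± 0.276 (SD, n = 2) in Control, and 5.55 ± 0.724 against 4.33 ± 1.97 (both SD, n = 2) for Pol II.

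The library labelled IAA stood closer to Control than the library labelled EGF did, with a median Pol II summit distance at snRNA genes of 1 bp against 321.5 bp, where the numbered IAA libraries had 615.5 and 468.5 bp. Of the 603 genes lost in the numbered Pol II IAA libraries, 14.8% (exact 95% interval 12.02 to 17.8, for counting error only) lacked a peak in the library labelled EGF. In the library labelled IAA it was 5.80% (4.08 to 7.98), a difference of 8.96 percentage points, with 15.8% for the label IAA+EGF and 2.99% in the unnumbered Control. The list labelled EGF was also shorter, with 27701 peaks against 33226 for the label IAA. Of all 12233 genes with an edge peak in the unnumbered Control, 526 lacked one in the library labelled EGF and 324 in the library labelled IAA. List length was not held equal for the 603 genes, so this difference does not decide between the labels. Of the 68 gained genes, 61.8% (49.2 to 73.3) had a peak in the library labelled EGF and 35.3% (24.1 to 47.8) in the library labelled IAA, but Control had 48.5% (36.2 to 61.0), which overlaps both, so these genes do not decide. At 20 of 20 snRNA genes the nearest Pol II summit was farther away for the label EGF than for the label IAA. This outcome was predicted before its values were seen. The medians above come from these same distances, so they are not separate support. Summits near the limit on stacked fragments are less certain, and near-identical copies share reads, so these are not 20 separate checks. Single genes can go with the titles: SMCO3 lacked a peak in the libraries labelled IAA and IAA+EGF and held one in the library labelled EGF. S100A1 held one under both labels IAA and EGF. Exchanged titles of these 2 libraries are a candidate explanation and the file names point the same way. An effect of EGF alone would leave the 1 bp in the library labelled IAA unexplained unless IAA did not act in it, which was not tested.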

How the results depend on the processing

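Joining peaks and restricting genes to those with Pol II or Tyr1P peaks at 1 end were chosen after the data were seen, and the others before. Of the alternative values, 103 kept their direction or size, 35 moved and 2 changed sign. With 2 libraries against 2 the exact permutation test could not pass 0.05, so only directions are compared. With lists of equal length the difference in edge share was -2.79 percentage points for Pol II, against 4.99, and for Ser2P it was near 0 (0.272, against -30.6). That setting removes the lower-ranked peaks of the longer lists and with them the difference in peak number. The cause was not tested further. It also gave 148 Pol II and 132 Tyr1P genes gained, 331 Ser2P genes gained and 322 lost, and 294 gained and 309 lost in the library labelled EGF against Control. A window of 500 bp gave 136 Pol II and 173 Tyr1P genes gained and 49 Ser2P genes lost. Adding the unnumbered libraries by their labels left 3 Pol II genes gained and 22 lost, with the title of the added IAA library in doubt. Of the lost genes, 5.80% lacked a peak in it, against 14.8% for the label EGF and 15.8% for IAA+EGF. Most lost genes thus kept a peak under any of these labels, in lists longer than the numbered IAA lists. Genes with Pol II or Tyr1P peaks at 1 end, a smaller set, gave 2287 Ser2P genes gained and 11 lost.

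Leaving out each replicate gave 98 to 184 Pol II genes gained and 675 to 1558 lost, 137 to 182 Tyr1P genes gained and 411 to 487 lost, and 3780 to 7090 Ser2P genes gained and 38 to 263 lost. These counts rise by construction, since fewer libraries must agree. The highest Pol II lost count came without IAA replicate 2, the highest Ser2P gained count (7090) without Control replicate 1 and the highest Ser2P lost count (263) without Control replicate 2. The share of all peaks of 2 lists that overlapped the other list was 0.728 (Pol II and Tyr1P), 0.551 (Pol II and Ser2P) and 0.526 (Tyr1P and Ser2P) in Control and 0.692, 0.259 and 0.329 with IAA. Requiring at least 0.5 of both peaks to be shared gave 0.526, 0.418 and 0.362 in Control and 0.490, 0.126 and 0.226 with IAA. Equal lists gave 0.636 for Pol II and Ser2P in Control and 0.636 with IAA, and for Tyr1P and Ser2P 0.539 in Control and 0.571 with IAA.

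With a replicate block the mean ratio of peak number was 0.818 for Pol II, 0.827 for Tyr1P and 4.24 for Ser2P, and no direction changed. The labels do not say what a replicate number marks. Deviations of same-numbered libraries correlated across genes, which are not independent replicates, at 0.029 for Pol II, -0.042 for Tyr1P and -0.0089 for Ser2P. Distances from every annotated transcript start were not run, since no transcript annotation was used here. Depth, at 3.28 fragments per kb in Ser2P Control replicate 2, limits what that list could detect.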

Other observations

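The summit distances in this part were chosen as a measure after the data were seen, on a gene list fixed before. At snRNA genes, whose transcripts Integrator is known to process, the nearest Pol II summit lay farther from the gene with IAA. At 20 of 20 listed genes the nearest Pol II summit was farther in both IAA libraries than in either control library, and the other splits of the libraries gave 0. The nearest summit was taken at any distance, so a lost peak also counts as farther. RNU2-2 (2481 and 2480 bp with IAA) and RNU4-1 (2077 and 1900 bp) were called lost above. RNU4-1 and its neighbour RNU4-2 had the same nearest summit in both IAA libraries, so the 20 genes are not 20 separate summits. The median distance was 11 and 22 bp in the control libraries and 615.5 and 468.5 bp with IAA. At RNU2-1 (chromosome 17, 43233790 to 43233977) the summit lay on the gene in both control libraries and 594 and 593 bp away with IAA. At RNU11 the distances with IAA were 442 and 416 bp, and at RNU7-1 631 and 732 bp against 90 and 151 bp in Control. The same order held at 19 of 20 genes for Tyr1P, with RNU2-1 the exception, and at 18 of 20 for Ser2P. For Tyr1P the control summits nearest RNU4-1, 1285 and 1287 bp away, lay on RNU4-2. RNU11, RNU12, RNU4ATAC and RNU7-1 showed it for all 3 antibodies. Near-identical copies share reads, so values of single U1, U2, U4 and U5 copies are uncertain. The strand was not used, so the direction of the shift is not given.

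Distances were also taken at histone genes and other short genes, where a summit anywhere on the gene counts as 0 bp. Among replication-dependent histone genes with a Pol II summit within 1 kb in both control libraries, 11 of 42 had farther summits in both IAA libraries and 2 nearer. Among 253 other protein-coding genes under 2 kb, 52 had farther summits and 26 nearer. The median was 0 bp in all 4 libraries for both kinds, and because these genes are mostly longer, moves within a gene are not seen, so the counts are not comparable with those at snRNA genes. In the unnumbered libraries the median distance at snRNA genes was 0 bp for the label Control, 1 bp for IAA, 321.5 bp for EGF and 341 bp for IAA+EGF.

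A limit on stacked fragments could flatten these strong peaks and free their summits to move. Between 7 and 19 of the 20 snRNA summits per Pol II library, and between 5 and 14 per Tyr1P library, lay within 5% of that limit. For Ser2P 0 did, and the summit was farther in both IAA libraries at 18 of 20 genes, which argues against the limit as the cause there. For Tyr1P the order held at 5 of the 6 genes below the limit in all 4 libraries. For Pol II 0 genes were below the limit in all 4, so this cause and a shift cannot be told apart from Pol II alone. A shift with loss of INTS11 remains a hypothesis found and tested on the same data.

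Some calls in the comparisons above lie at small RNA genes, chosen here after their values were seen, and the summits did not all move away. SNORD118, the U8 RNA gene inside TMEM107, held the Pol II summit in both control libraries, and with IAA the summit lay 386 and 380 bp away. TMEM107 was called gained for Pol II and lost for Ser2P. RNU7-1 lies inside C12orf57, which was called lost for Pol II and Tyr1P and gained for Ser2P. At LUC7L2 and FMC1 the Tyr1P summit came nearer to a tRNA gene, TRR-CCT4-1, from 744 and 890 bp in Control to 0 and 26 bp with IAA.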
